A study of Mus musculus with 4 samples.

How the data were processed

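Polyadenylated RNA of 4 mouse libraries was analysed, all from cells of the lower incisor at postnatal day 30: 2 controls with floxed Ptip alleles and 2 conditional knockouts with the same alleles and Sp7-cre. Per the labels' protocols, cells negative for CD45, Ter119 and Tie2 were sorted by flow cytometry, cDNA was made with oligo-dT primers and template switching and amplified in 14 PCR cycles, and 50 ng of it were fragmented with a transposase kit. Such libraries do not mark strand or molecules, so PCR copies cannot be told from separate molecules, and reads of overlapping antisense genes cannot be told apart. The deposited values are whole-number counts per Ensembl gene ID for the 4 libraries in 1 table, not normalised. Per the submitters' processing notes, Trim Galore 0.6.6, Bowtie2 2.3.5.1, featureCounts 2.0.1 and the GRCm38 build were used. The annotation release, the strand setting, the treatment of reads with several matches and the mode of the aligner are not given in the sources used here. All columns of the table belonged to the 4 libraries, and each was matched to its sample by name. Groups and replicate numbers were taken from the sample titles and genotypes.

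The table held 55487 genes, of which 55227 were found by ID in GENCODE mouse release M21 (GRCm38), which gave symbols and coordinates. Of these, 31364 had a count in at least 1 library. Where several IDs shared a symbol, the one with the most counts kept it. Library totals were 15154246 and 15394782 counts in controls 1 and 2, and 19142757 and 17770831 in knockouts 1 and 2. The 10 most abundant genes of each library took 8.86% to 13.6% of its counts. A count of 3 corresponds to 0.157 to 0.198 CPM, and such figures cover counting error only. The libraries of a group differed by far more than sampling noise (chi-square per gene of 148 between the controls and 88.8 between the knockouts), so no library was a copy of another. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.898 between the controls, 0.926 between the knockouts and 0.809 to 0.901 between groups.

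The test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with TMM normalisation and genotype as the only term. It ran on the 17128 genes kept by filterByExpr, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use TMM-scaled library sizes. The SE of a log2 fold change is its absolute value divided by the square root of F. Fold changes are the fitted ones, with the knockout over the control. The biological coefficient of variation was 49.2%. With no Cre in the controls, the loss of Ptip and the presence of the Cre transgene differ between the same samples. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were alternatives. In edgeR without the low-count filter, the estimated prior degrees of freedom were infinite. A gene's own spread then did not enter its p, so p-values of that fit can be far too small. Adjusted p-values that DESeq2 left empty were kept empty, which left 17378 genes with one.

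Before the data were examined, 32 gene lists were fixed for Wnt and other pathways, the tooth tissues, cell states and other cell types. Of their 563 places, 528 were filled by tested genes, with 5 to 32 per list. Lists were tested with camera at its preset correlation of 0.01, adjusted over the 32 lists. Also fixed were the alternatives in scaling, filter, test, threshold, replicate block and libraries. With the correlation estimated from the data, none of the 14 calls held. That form of camera draws its degrees of freedom from the 4 libraries alone, so passing over 32 lists was all but out of reach. Even the erythroid list, with an estimated correlation of -0.040, below the preset, had p = 0.0190 (adjusted p = 0.608). These losses thus do not show that correlation between genes accounts for the calls. They do not exclude it either. The estimate was far above the preset for cell cycle genes (0.492), leukocyte markers (0.605), collagens (0.539) and dental mesenchyme genes (0.198), among others. It was below the preset also for the chondrocyte, muscle and cell cycle inhibitor lists. Where it was far above, camera p-values at the preset can be too small. The test named fry, which asks whether a list's genes move one way on balance, called 0 lists. Its mixed form, which asks whether they change in either direction, called 10. Among these were the dental mesenchyme, BMP and TGF-beta, erythroid, Schwann cell and chondrocyte lists. The rest were lists that camera did not call: Wnt feedback and targets, Wnt ligands, odontoblast, Notch and p53. The cell cycle, leukocyte and collagen lists did not pass the mixed form (adjusted p = 0.110, 0.127 and 0.119). Within a list, p-values were also adjusted over the list alone. A member is counted as higher or lower in both knockouts when both lie above or below both controls. Leaving a library out leaves a group with 1 sample, which is assumed to vary like the other group.

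The genes to be named were set by a rule fixed before the data were examined. It named Paxip1 and a panel of 22 genes whatever their result, the called genes with the largest changes, and, if none passed, the 5 with the smallest p in each direction. No gene passed, so the last part applied. A gene that this part names is not reported here. Other genes named as examples of a list were chosen after their values were seen, from the 4 members of each list with the smallest p in most cases. The other genes outside the rule were also chosen after their values were seen. Genes with near-identical copies, such as the haemoglobin pairs and Bglap with Bglap2, are uncertain.

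The steps were tested on simulated data, drawn for the 17128 genes from the real means, library sizes and fitted dispersions. At each of 4 sizes, 50 genes were changed, taken from the more abundant genes outside the lists. At 2-, 4-, 8- and 16-fold, edgeR recovered 1, 29, 46 and 49 of 50 genes, with 16 false calls among 142. DESeq2 recovered 3, 37, 47 and 49, with 55 false calls among 194. The other calls, 1 by edgeR and 3 by DESeq2, were genes of the shift planted in the cell cycle list. With no gene changed, edgeR called 0 genes and DESeq2 called 25. Camera found a shift planted in the cell cycle list and called 0 other lists. The simulated genes were independent of each other, so this does not test camera under correlated genes. The fitted dispersions are already evened out between genes, so the simulated spread is more even than the real one. The recovered shares thus do not carry over to the real data. There no gene passed in edgeR, and Apod, 15.8-fold higher, had an adjusted p of 0.145.

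For the closing observations, the longest coding transcript of each cytosolic ribosomal protein gene was compared with all annotated transcripts by blastn 2.17.0. Other genes with a match of at least 95% identity over 200 bases were counted as near-identical copies. Spearman correlations across those genes used 100000 permutations (SciPy 1.17.1).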

Results

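RNA was sequenced from sorted cells of the mouse lower incisor, a tooth that grows throughout life and keeps progenitor cells at its root end. Cells taken as dental progenitors at postnatal day 30 were sorted as negative for CD45, Ter119 and Tie2. These are surface proteins of leukocytes, erythroid cells and endothelial cells. This gate selects for no progenitor marker, and genes of ameloblasts and blood cells were also counted. There were 2 groups of 2 libraries. The controls carried floxed Ptip alleles without Cre, and the conditional knockouts carried the same alleles with Cre driven by Sp7, a transcription factor gene of the bone and odontoblast lineages. Ptip, whose gene symbol is Paxip1, encodes a subunit of the KMT2C and KMT2D histone H3 lysine methyltransferase complexes. The series title ties the gene to tooth development through the Wnt pathway, so Wnt genes were examined as separate lists. The libraries held 15154246 and 15394782 counts in controls 1 and 2, and 19142757 and 17770831 in knockouts 1 and 2.

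Paxip1 was lower in both knockout libraries. The gene (ENSMUSG00000002221) lies on chromosome 5 from 27740080 to 27791691 on the minus strand of GRCm38. It had 407 and 696 counts in the controls and 111 and 71 in the knockouts. Normalised expression was 36.3 ± 11.3 on the counts-per-million scale (CPM; SD, n = 2) in controls and 4.83 ± 1.21 (SD, n = 2) in knockouts, a 7.50-fold lower level (log2 fold change -2.91, SE 0.48). The adjusted p was 0.150 in edgeR's quasi-likelihood test, which did not pass 0.05, 1.4e-05 in edgeR without the low-count filter and 9.0e-06 in DESeq2. The adjusted p did not pass in limma-voom (0.0811), or in edgeR with the stricter filter (0.0691) or the replicate block (0.0575). With 1 library left out, the log2 fold change ranged from -2.59 (without control 2) to -3.18 (without knockout 1). The counts cover all annotated exons of the gene, so exons outside the deleted part can still contribute. Among 9 tested members of the KMT2C/KMT2D complexes, 5 were lower and 1 was higher in both knockouts than in both controls, and the list did not pass the test (adjusted p = 0.284). Kmt2c stood at 39.8 ± 10.3 CPM in controls and 27.0 ± 1.56 in knockouts (SD, n = 2 each). Kmt2d stood at 132 ± 49.2 against 127 ± 44.3, and Kdm6a, which encodes an H3K27 demethylase, at 51.2 ± 26.5 against 38.5 ± 11.6. Kmt2d and Kdm6a changed sign when control 2 was left out (0.36 and 0.20), and Kmt2d also without knockout 1 (0.28).

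No gene passed the edgeR test, so the genes with the smallest p in each direction are given. The 5 genes with the smallest p among those higher in the knockout were Slc12a1, Apod, Nqo1, Foxf1 and Ccsap, and none of them passed (adjusted p = 0.145 for each). Slc12a1, a sodium-potassium-chloride cotransporter best known from the kidney, was 13.3-fold higher (8.74 ± 1.15 against 116 ± 14.5 CPM). Apod, which encodes apolipoprotein D, was 15.8-fold higher (194 ± 77.9 against 3076 ± 528 CPM). Nqo1, a quinone reductase, was 7.44-fold higher, Foxf1, a mesenchymal forkhead factor, 6.77-fold and Ccsap 13.1-fold. Among the 5 with the smallest p on the lower side were Atp2a3, Mpo, E2f2 and Gfra2, which also had an adjusted p of 0.145 each. Mpo, the myeloperoxidase of neutrophil precursors, was 8.03-fold lower (233 ± 76.2 against 29.1 ± 4.34 CPM). E2f2, a cell cycle transcription factor, was 8.01-fold lower, Atp2a3, a calcium pump gene, 8.92-fold and Gfra2, a neurturin receptor gene, 7.03-fold. These 9 genes passed in DESeq2 (adjusted p of 1.8e-06 or less). They also passed in edgeR without the filter (6.4e-06 or less) and with the replicate block (0.0414 or less). None of them passed in limma-voom (0.0559 or more) or in edgeR with the stricter filter (0.0691). Each kept its direction with 1 library left out.

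Over 17128 tested genes, edgeR called 0 genes higher and 0 lower at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 1254 higher and 1694 lower genes, where 856.4 in all would be expected by chance. DESeq2 called 472 genes higher and 989 lower. With the replicate block, for which the labels name no pairing, edgeR called 59 higher and 185 lower. In 50.6% of genes the 2 groups did not overlap, against 33.3% by chance. Leaving out control 2 kept edgeR at 0 in both directions, whereas it called 95 higher and 214 lower without control 1, 215 and 703 without knockout 1, and 15 and 1 without knockout 2. The labels do not say whether the libraries came from separate animals. The X-linked Xist had 116 CPM in knockout 1 and 5.83 in knockout 2, and the Y-linked Uty 0.256 and 31.7. In controls 1 and 2, Xist had 58.3 and 211 CPM and Uty 13.2 and 2.93. Sex-linked genes thus differed between the libraries of each group, which argues against technical repeats of the same cells. Control 1 had Xist (838 counts) together with the Y-linked Ddx3y (620), Eif2s3y (660) and Uty (190). This argues against cells of a single animal in control 1, though carry-over between libraries was not tested. For the other libraries, a single animal or a pool stays open. The p-values measure the spread between these samples. It includes the difference in sex-linked genes and may be technical in part.

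Among the lists that were higher in the knockout, dental mesenchyme and progenitor genes had the smallest p. Of 25 tested members, 13 were higher and 3 lower in both knockouts than in both controls, and the median log2 fold change was 0.67. The list passed camera, the list test (adjusted p = 0.000265), but not with an estimated correlation (adjusted p = 0.640 with an estimated correlation). With 1 library left out the median ranged from 0.49 (without control 1) to 1.46 (without control 2), and the list passed each time (adjusted p of 0.0155 or less). By edgeR, 9 members were higher and 1 was lower adjusted over the list alone, and none over all genes. Msx1, a homeobox gene of the tooth bud mesenchyme, was 3.46-fold higher (786 ± 86.3 against 2718 ± 273 CPM, SD, n = 2 each). It passed over all genes in DESeq2 (adjusted p = 0.000403), and in edgeR without the filter (0.000993) and with the replicate block (0.0465). It did not pass in limma-voom (0.0761) or in edgeR with the stricter filter (0.0785). Msx2 was 4.99-fold higher (84.4 ± 4.24 against 422 ± 88.1 CPM), Lhx6, a LIM homeobox gene, 4.10-fold and Twist2 3.78-fold. Pax9 stood at 28.3 ± 1.01 CPM in controls and 43.8 ± 2.46 in knockouts. Gli1, a hedgehog target that marks incisor stem cells, stood at 11.7 ± 5.24 and 17.3 ± 0.75. Its log2 fold change was 0.57, and 1.14 without control 1 and 0.14 without control 2. The leukocyte, erythroid and endothelial lists moved the other way between the same groups, with medians of -1.40, -2.08 and -0.64.

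**Figure D1:**
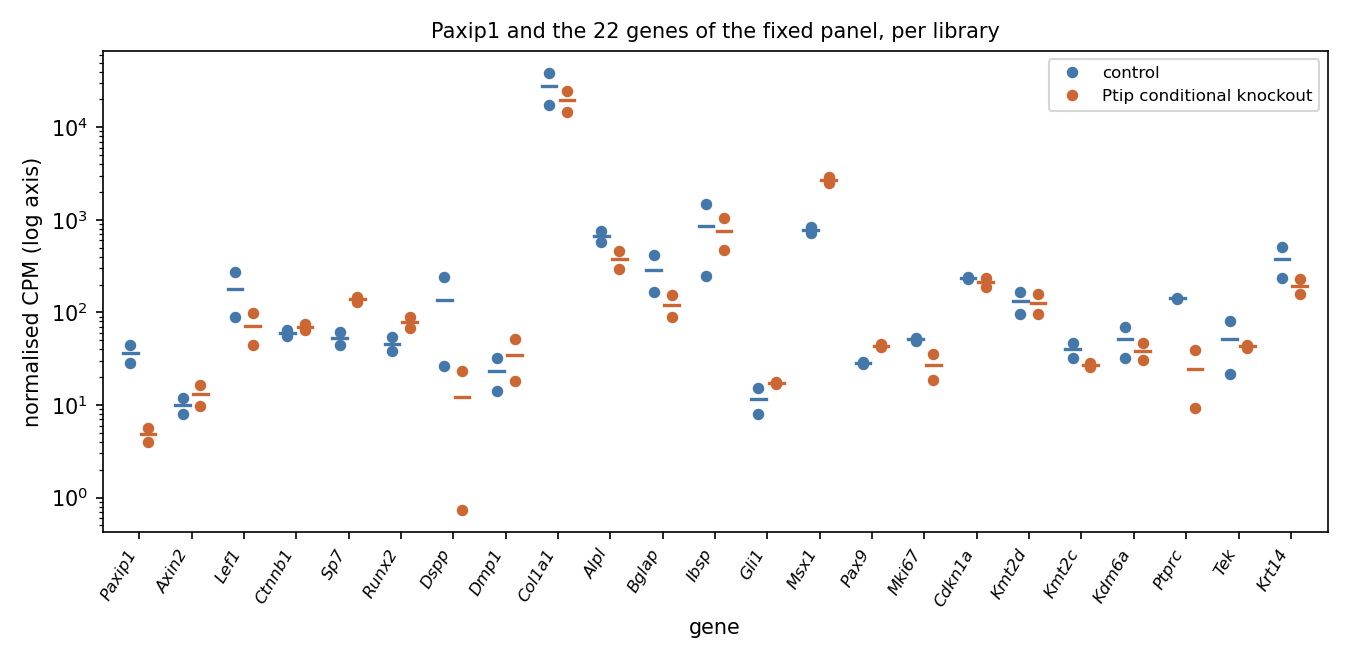
Normalised CPM on a log axis for Paxip1 and the 22 genes of the fixed panel, with 1 point per library, blue for the 2 controls and orange for the 2 knockouts, and a bar at each group's mean. Paxip1 lies between 3.98 and 5.69 CPM in the knockouts and between 28.3 and 44.3 in the controls, Msx1 is higher in both knockouts, and Dspp spreads from 0.73 to 244 CPM.

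BMP and TGF-beta pathway genes leaned higher in the knockout, with 13 of 29 tested members higher and 3 lower in both knockouts than in both controls. The median log2 fold change was 0.52 (camera adjusted p = 0.0150, and adjusted p = 0.640 with an estimated correlation). The call was lost without control 1 (median 0.25, adjusted p = 0.212). Bmp7 was 2.97-fold higher (56.5 ± 0.15 against 168 ± 2.97 CPM). Nog, an extracellular antagonist of BMP, was 7.63-fold higher (2.95 ± 1.41 against 22.6 ± 6.35 CPM), and Smad6, an intracellular inhibitor of the pathway, 3.53-fold. These 3 were the members higher adjusted over the list alone. Cartilage genes were also higher, with 6 of 10 members above and 2 below the controls in both knockouts. Their median was 0.93 (camera adjusted p = 0.00330, and adjusted p = 0.623 with an estimated correlation), and 4 were higher adjusted over the list alone. Col9a3 was 7.46-fold higher, Col9a2 4.88-fold, Hapln1 4.79-fold and Col9a1 3.58-fold. The chondrocyte call was lost without knockout 2 (adjusted p = 0.0645, median 0.04).

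Wnt genes went in both directions. Wnt receptors and co-receptors were the one Wnt list of 5 that passed camera, with 10 of 18 members higher and 1 lower in both knockouts. The median was 0.66 (adjusted p = 0.0231, and adjusted p = 0.649 with an estimated correlation), and the call was lost without control 1 (median 0.39, adjusted p = 0.390) and without knockout 2 (adjusted p = 0.0986). The median was 1.16 without control 2, and the adjusted p was smaller in a split by replicate number than by genotype. Fzd9, a frizzled receptor, was 10.9-fold higher (1.56 ± 0.04 against 17.1 ± 14.5 CPM) and Ror2, a receptor for Wnt5a, 4.63-fold higher (9.29 ± 0.63 against 43.1 ± 31.2 CPM). Lgr5, an R-spondin receptor and a target of the pathway, was 8.39-fold lower (86.2 ± 55.9 against 10.3 ± 6.66 CPM). These 3 passed adjusted over the list alone.

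The list of Wnt/beta-catenin feedback and target genes did not pass camera (median 0.30, and 0.15 to 0.68 with 1 library left out, adjusted p = 0.342). In fry's mixed form it passed, as did the Wnt ligands (adjusted p = 0.0409 for each). Of the 18 feedback and target genes, 7 were higher and 5 lower in both knockouts. Adjusted over the list alone, 2 were higher and 1 lower. Notum, a secreted Wnt deacylase, stood at 1.38 ± 0.57 CPM in controls and 12.6 ± 3.44 in knockouts, and Bambi at 379 ± 96.4 and 1197 ± 127. Axin2 stood at 9.91 ± 2.81 CPM against 13.2 ± 4.69 (log2 fold change 0.41, SE 0.52) and Lef1 at 179 ± 129 against 72.0 ± 38.7 (-1.32, SE 0.62). Ctnnb1, the gene of beta-catenin, stood at 60.1 ± 7.05 CPM against 69.9 ± 6.64. None of these 3 passed in edgeR (adjusted p = 0.759, 0.338 and 0.805) or in DESeq2, and Lef1 passed without the low-count filter (0.0325). Lef1 was -0.27 without control 1 (adjusted p = 0.884) and -1.96 without control 2, and Axin2 was 0.034 without knockout 2. Wnt ligands did not pass camera either (adjusted p = 0.631). The ligands had a median of 0.13 and a mean of -0.43, with 8 of 20 members higher against 5 lower. Their median was -0.39 without control 1, -0.07 without knockout 2 and 0.82 without control 2. Wls, which carries Wnt proteins to the cell surface, was at 228 ± 49.7 CPM in controls and 761 ± 8.97 in knockouts, whereas Wnt2 was at 7.94 ± 4.25 and 0.61 ± 0.15. The Wnt antagonists (adjusted p = 0.385, median 0.02) and the intracellular components (adjusted p = 0.146, median 0.22) did not pass, except the former without control 2 (0.0337) and the latter without knockout 1 (0.0384) or without the filter (0.0449). The antagonist median was 0.87 without control 2, -0.34 without control 1 and -0.36 without knockout 1. Wnt ligands passed with the stricter filter (0.0303). Frzb, a secreted antagonist, had 50.1 ± 25.9 CPM in controls and 193 ± 2.07 in knockouts.

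The odontoblast and dentin list did not pass camera, but passed fry's mixed form (adjusted p = 0.0463). Of 23 tested members, 7 were higher and 6 lower in both knockouts. The median was 0.14, the mean -0.08 and the camera adjusted p 0.525. The median was -0.35 without control 1, -0.32 without knockout 2 and 0.92 without control 2 (adjusted p = 0.0769). Sp7 itself was 2.64-fold higher (52.3 ± 11.9 against 138 ± 10.5 CPM), with an adjusted p of 0.165 in edgeR, 0.0259 in edgeR without the filter and 0.0211 in DESeq2. Whether the Cre transgene adds counted Sp7 sequence is not given in the labels. Runx2 stood at 46.0 ± 11.2 CPM in controls and 79.0 ± 14.5 in knockouts, and Panx3, a channel of the bone and odontoblast lineages, at 6.53 ± 2.65 and 31.0 ± 8.55. Dspp, the dentin sialophosphoprotein gene of mature odontoblasts, ranged from 26.2 to 244 CPM in controls and from 0.73 to 23.5 in knockouts (log2 fold change -3.47, SE 1.52, adjusted p = 0.306). Dspp passed without the low-count filter (-3.51, adjusted p = 6.9e-11), but that fit takes no account of the gene's own wide spread. Without knockout 1 the Dspp value was -7.51, with an adjusted p of 7.6e-07, and without control 1 it was -4.29 (adjusted p = 0.0374). It was -1.18 without control 2 (adjusted p = 0.670) and -2.48 without knockout 2 (adjusted p = 0.278). Alpl stood at 668 ± 132 against 376 ± 115 CPM and Bglap, which is uncertain because reads could match its near-identical copy Bglap2, at 289 ± 176 against 121 ± 45.5. Bglap passed without control 1 (adjusted p = 0.0447) and without the filter (0.0479), and its log2 fold change of -1.26 was -0.47 without control 2 (adjusted p = 0.588). Dmp1, Ibsp and Col1a1 overlapped between the groups, and each changed sign when 1 library was left out (Dmp1 -0.32 without knockout 2, Ibsp 1.59 and Col1a1 0.15 without control 2, and Ibsp 0.30 without knockout 1).

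Collagen genes and periodontal ligament and tendon markers were lower in the knockout. Of 21 collagen genes, 10 were lower and 1 higher in both knockouts, with a median of -0.95 (camera adjusted p = 2.7e-05, and adjusted p = 0.640 with an estimated correlation). Adjusted over the list alone, 4 were lower. Col18a1, a basement membrane collagen, was 3.42-fold lower (141 ± 23.7 against 41.2 ± 3.55 CPM), Col5a3 5.74-fold, Col14a1 7.52-fold and Col15a1 10.9-fold. The collagen call was lost without control 2 (median -0.31, adjusted p = 0.0975). Endothelial and Schwann cell markers were also highest in that library: the list medians of log2 CPM, centred per gene, were 0.96, 0.69 and 0.99 in control 2 for collagens, endothelial and Schwann cell markers, and below 0 in both knockouts. Among 11 periodontal ligament and tendon markers, 7 were lower and 2 higher, with a median of -1.90 (adjusted p = 0.00494, and adjusted p = 0.640 with an estimated correlation). Tnc, the gene of tenascin C, was 5.71-fold lower (337 ± 94.8 against 59.0 ± 3.42 CPM) and Cilp 10.6-fold lower. Fmod, the gene of fibromodulin, was 3.77-fold higher (607 ± 37.5 against 2286 ± 92.9 CPM). This call too was lost without control 2 (median -1.03, adjusted p = 0.274).

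Cell cycle genes were lower in the knockout across the list. All 32 members had negative fold changes, and 29 were lower in both knockouts than in both controls. The median was -1.25 (camera adjusted p = 1.5e-13, and adjusted p = 0.623 with an estimated correlation), and 16 members were lower adjusted over the list alone. Kif11, a spindle motor, was 4.86-fold lower (88.5 ± 3.00 against 18.2 ± 2.56 CPM), Mcm3, a replication helicase subunit, 3.93-fold, Top2a 2.93-fold and Bub1b 2.83-fold. Mki67 stood at 51.3 ± 2.43 CPM in controls and 27.2 ± 12.2 in knockouts (log2 fold change -0.92, and -0.47 without knockout 2). Of the cell cycle inhibitors and senescence genes, 7 of 14 were lower and 0 higher in both knockouts, with a median of -0.59 (adjusted p = 0.0192, and adjusted p = 0.623 with an estimated correlation). The members lower adjusted over the list alone were Lmnb1, a nuclear lamin gene that proliferating cells express (5.05-fold), and Cdkn2d, a CDK inhibitor gene (2.75-fold). With a gene of proliferating cells among its members, the direction of the list does not speak to senescence. That call was lost without knockout 1 (adjusted p = 0.0823). Cdkn1a, the p21 gene, stood at 234 ± 10.4 and 212 ± 30.6 CPM and changed sign without knockout 2 (0.04). The p53 and apoptosis list had a median of -0.34 (camera adjusted p = 0.0627, and adjusted p = 0.0471 in fry's mixed form). It passed in limma-voom (0.0357), without the filter (0.0497) and with the stricter one (0.0488), and not with 1 library left out (0.0645 to 0.252). Blood genes differed between the same libraries: the summed CPM of the leukocyte list was 6032 and 1884 in controls 1 and 2 and 1026 and 317 in knockouts 1 and 2, and that of the erythroid list was 632, 553, 114 and 157.

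Markers of the erythroid, leukocyte and endothelial cells that the gate was meant to remove were lower in the knockout. All 11 erythroid markers were lower in both knockouts (median -2.08, camera adjusted p = 1.5e-10, and adjusted p = 0.608 with an estimated correlation), 8 of them adjusted over the list alone. Klf1, an erythroid transcription factor gene, was 5.37-fold lower, and Hba-a1, a haemoglobin gene that is uncertain because reads could match its near-identical copy Hba-a2, 4.53-fold lower (173 ± 10.2 against 38.1 ± 0.09 CPM). Of 21 leukocyte markers, 14 were lower in both knockouts and 0 higher (median -1.40, adjusted p = 9.1e-09, and adjusted p = 0.640 with an estimated correlation), 7 of them adjusted over the list alone. Their median was -0.88 without control 1 and -2.30 without knockout 1. Ptprc, which encodes the sorted marker CD45, was 5.87-fold lower (142 ± 2.58 against 24.2 ± 21.1 CPM). Its log2 fold change of -2.55 was -3.93 without knockout 1 and -1.81 without knockout 2. Over all genes, Ptprc passed in edgeR without the filter (adjusted p = 7.4e-07) and in DESeq2 (0.000534). It did not pass in limma-voom (0.0866) or in edgeR with the replicate block (0.0881). Elane, the neutrophil elastase gene, was 11.9-fold lower. Endothelial markers had a median of -0.64 with 9 of 15 lower in both knockouts (adjusted p = 0.0150, and adjusted p = 0.651 with an estimated correlation), and 0 passed adjusted over the list alone. Tek, the gene of the sorted marker Tie2, stood at 51.5 ± 42.1 and 43.3 ± 2.15 CPM and changed sign without control 2 (0.96). The endothelial call was lost without control 2 (median -0.15, adjusted p = 0.456) and without knockout 1 (adjusted p = 0.0644).

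Dental epithelium and ameloblast markers had a median of -0.95, with 9 of 18 lower and 0 higher in both knockouts (adjusted p = 0.00455, and adjusted p = 0.640 with an estimated correlation). None passed adjusted over the list alone, and the call was lost without control 1 (median -0.33, adjusted p = 0.214). The adjusted p was smaller in a split by replicate number than by genotype. Krt14, a basal keratin gene, stood at 375 ± 197 and 193 ± 51.2 CPM (log2 fold change -0.96, and -0.27 without control 1), and Klk4, an enamel protease gene, at 8.50 ± 1.94 and 1.45 ± 1.42. Schwann cell and nerve markers split: 6 of 12 were lower adjusted over the list alone, among them Prx (3.63-fold) and Mbp (3.23-fold), and 3 were higher in both knockouts. Their median was -0.72 (adjusted p = 0.0150, and adjusted p = 0.623 with an estimated correlation), and the call was lost without control 2 (adjusted p = 0.158), without knockout 1 (median -1.56, adjusted p = 0.0788) and in limma-voom (adjusted p = 0.0545). Skeletal muscle markers were low throughout, with 6 of 8 lower in both knockouts and a median of -1.71 (adjusted p = 0.0155, and adjusted p = 0.623 with an estimated correlation). Acta1 was at 5.79 ± 1.44 and 1.83 ± 0.19 CPM, and 0 members passed adjusted over the list alone. The muscle call was lost without control 2 (median -1.11, adjusted p = 0.158) and without knockout 1 (adjusted p = 0.0543).

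**Figure D2:**
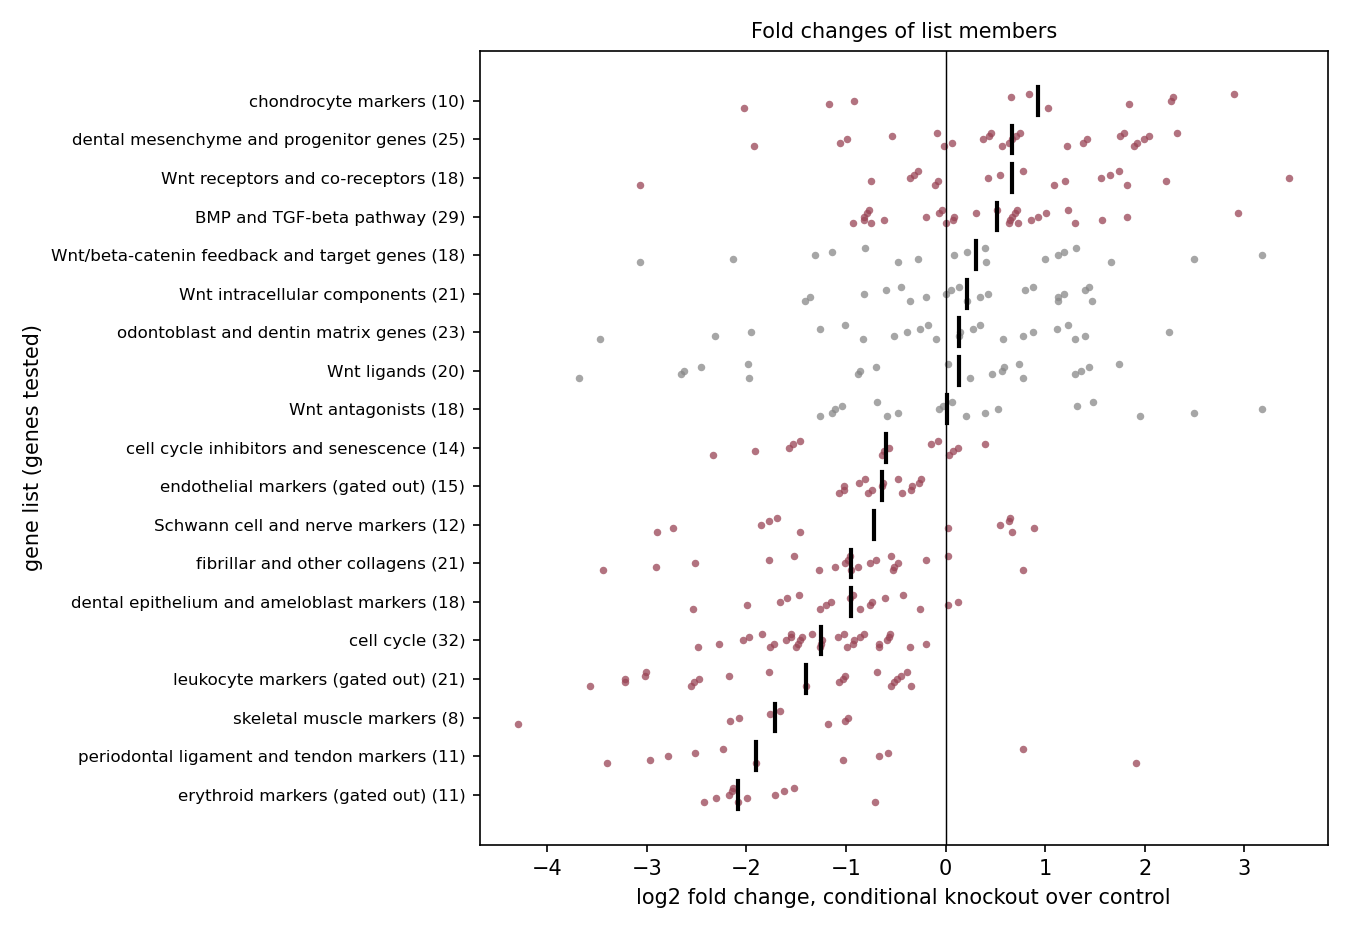
Log2 fold change (knockout over control) of every tested member of 19 gene lists, 1 point per gene, with the number of genes tested after each name and a black bar at the list median. Red lists passed camera with its preset correlation and grey lists did not. All 32 cell cycle genes lie below 0, and the erythroid list has the lowest median, -2.08.

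The other 11 lists did not pass camera, though the Notch list passed fry's mixed form (adjusted p = 0.0409). The Notch list had a median of -1.13 and an adjusted p of 0.0532, with 9 of 17 members lower and 3 higher in both knockouts. The median was -0.52 without control 2 (adjusted p = 0.255) and -0.67 without knockout 1 (adjusted p = 0.299), and the list passed without the filter (0.0349) and with the stricter one (0.0458). Heyl, a Notch target, stood at 60.7 ± 15.6 CPM in controls and 14.2 ± 3.69 in knockouts, and Hey1, another target, at 74.9 ± 7.44 and 169 ± 14.7. FGF genes (adjusted p = 0.284, median 0.36) included Fgfr2, at 31.3 ± 7.25 and 129 ± 55.4 CPM, and Dusp6, at 295 ± 27.0 and 116 ± 63.6. Their median was -0.29 without knockout 1, -0.02 without control 1 and 0.88 without control 2. In the hedgehog list (adjusted p = 0.579), Gli2 stood at 12.6 ± 1.47 and 29.2 ± 0.33 CPM. Immediate early and dissociation stress genes (adjusted p = 0.813), interferon-stimulated genes (0.837), glycolysis genes (0.146) and mitochondrially encoded genes (0.880) did not pass. Neither did pericyte and smooth muscle (0.641), osteocyte (0.880) or osteoclast markers (0.606), or the sex-linked genes (0.659). The medians of these lists and of the hedgehog list moved with single libraries and are left out. Leaving out control 1 made the Notch (adjusted p = 0.0251), immediate early (0.0155) and glycolysis lists (0.0220) pass, the last also without the filter (0.0497). Leaving out knockout 2 did so for the Notch (0.0213), pericyte (0.0213), interferon (0.0327) and sex-linked lists (0.00163).

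The list calls carry a limit, seen when the libraries are grouped in another way. When the 4 libraries were split by replicate number instead of genotype, camera called 12 lists, against 14 for the genotypes. DESeq2 called 6 genes by number, against 1461, and edgeR called 0 in both splits. A split that mixes genotypes holds the genotype difference within its groups, so few gene calls were to be expected there. The gene counts therefore do not show that the 1461 calls are sound. The erythroid, chondrocyte, cell cycle inhibitor, endothelial, Schwann cell and muscle lists passed in the genotype split only, and the cell cycle list had an adjusted p of 0.000921 in the split by number. Of the 8 called in both, 2 had a smaller adjusted p by number than by genotype. These were the Wnt receptors (0.00172 against 0.0231) and the dental epithelium (0.000123 against 0.00455). Also called by number were the collagens (7.8e-05 against 2.7e-05), leukocyte markers (3.5e-06 against 9.1e-09) and dental mesenchyme genes (0.00842 against 0.000265). So were the periodontal ligament (0.00611 against 0.00494) and BMP and TGF-beta lists (0.0320 against 0.0150).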

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

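The counts of called genes depended on the test, the filter and the libraries, and the cause was not tested. Against 0 higher and 0 lower genes as reported, DESeq2 called 472 and 989, edgeR without a low-count filter 449 and 1005, and edgeR with the replicate block 59 and 185. Leaving out 1 library gave 0 to 215 higher and 0 to 703 lower genes. The other scalings, limma-voom, the stricter filter, the removal of mitochondrial, haemoglobin and leukocyte genes and the other thresholds left both counts at 0. The prior degrees of freedom that edgeR estimated were 4.85 as reported, 14.5 without control 1, 97.9 without knockout 1 and 28.0 without knockout 2. Without the low-count filter they were infinite, so that fit set aside each gene's own spread. Replicate numbers are shared by 2 pairs of libraries. The labels do not say that a number marks a shared litter or day, and the correlation of same-numbered deviations was 0.15, so the numbers are not read as pairs. Something shared by same-numbered libraries cannot be excluded, since the split by number called 12 lists and the remaining mixed split 6. The remaining split also divides the libraries by sex-linked genes, so it is no neutral reference.

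Paxip1 was lower under each alternative. It passed with DESeq2 (-2.92, adjusted p = 9.0e-06) and without the filter (-2.92, 1.4e-05), and ranged from -2.59 to -3.18 when 1 library was left out. Of 14 called lists, 8 passed at an adjusted p of 0.01, 0 with an estimated correlation and 0 with fry's directional test, and 10 to 16 lists passed with 1 library left out. The cell cycle, dental mesenchyme, leukocyte and erythroid lists passed in all fits that could test them, apart from the estimated correlation and fry. Of 414 refits of the other 32 named genes, 331 gave the same direction and call, 70 also passed the threshold and 13 changed sign, and in each of those 13 the value was not called. With limma-voom, Ibsp was 0.21 and Tek 0.028, and with the replicate block 0.21 and 0.036. With 1 library left out, Ibsp ranged from -0.93 to 1.59, Tek from -0.88 to 0.96, Dmp1 from -0.32 to 1.28, Col1a1 from -0.97 to 0.15, Cdkn1a from -0.29 to 0.039, Kmt2d from -0.42 to 0.36 and Kdm6a from -0.83 to 0.20. The median log2 fold change of all genes was -0.21 without the filter and -0.11 without knockout 1, against 0.0024 as reported.

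The 4 libraries can be split into pairs in 3 ways, too few for a share under 0.05. The genotype split gave 1461 DESeq2 calls and 14 lists, and edgeR called 0 genes in each split. The split by replicate number gave 6 DESeq2 calls and 12 lists, and the remaining split 5 calls and 6 lists. The remaining split set control 1 and knockout 2 against control 2 and knockout 1. It also divides the libraries by sex-linked genes. Ddx3y had 43.1 and 117 CPM against 8.85 and 2.0, and Xist 58.3 and 5.83 against 211 and 116. The sex-linked list had a camera adjusted p of 3.2e-11 there, so this split is no neutral reference. Groups did not overlap in 5278 genes by replicate number and in 3177 in the remaining split, against 8673 by genotype. Every tested gene falls in a single split by this measure, so the counts share a fixed total of 17128. A higher count by genotype thus lowers the others. Of the 14 lists, 8 were also called in another split and 6 were not.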

Other observations

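The genes given here were chosen after their values were seen, from those with non-overlapping groups among the 210 genes with a mean of at least 500 CPM. None passed in edgeR. Ldhb, a lactate dehydrogenase subunit gene, was at 434 ± 195 CPM in controls and 4125 ± 1217 in knockouts (SD, n = 2 each). Angpt4, an angiopoietin gene, was at 239 ± 35.8 and 1512 ± 97.2, Tgfbi, an extracellular matrix gene, at 262 ± 28.8 and 1449 ± 317, and Serpinf1, the gene of pigment epithelium-derived factor, at 977 ± 147 and 3913 ± 838. On the low side, Ighm, the IgM heavy chain gene, had 8369 and 3123 CPM in controls 1 and 2 and 1191 and 210 in knockouts 1 and 2. Cd79a, a B cell receptor gene, had 1744, 362, 188 and 37.4 in the same order. Slc1a5, a glutamine transporter gene, was at 1191 ± 77.2 and 258 ± 92.2.

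Some values stood apart in single libraries. Ambn, the ameloblastin gene, had the highest share of counts in 3 libraries, up to 4.99%, but was below Col1a1 and Col3a1 in control 2 (1.85%). It had 41111 CPM in knockout 2. The other enamel matrix genes Amelx and Enam had 80.0 and 77.2 CPM in that library, against 2395 to 7422 and 970 to 1498 in the other 3. Barx1, a molar mesenchyme homeobox gene, had 0, 1, 3 and 120 counts in controls 1 and 2 and knockouts 1 and 2 and was removed by the low-count filter. Xist, which is expressed from the inactive X, had 58.3, 211, 116 and 5.83 CPM in that order, and the Y-linked Ddx3y had 43.1, 8.85, 2.0 and 117.

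The tests of the cell cycle and dental mesenchyme patterns were chosen only after the results were seen, and those of ribosomal protein genes before. The first pattern is the lower level of cell cycle genes in the knockout. The tables do not argue against leukocytes in the controls as a source. Control 2 lacked a part of control 1's excess over the knockout mean. That part had a median of 0.50 for cell cycle genes (quartiles 0.01 and 0.62) and 0.77 for leukocyte genes (0.34 and 0.85). These quartile ranges overlap widely, so the comparison could hardly have argued against that source. Leukocyte genes also differed among themselves: Ptprc had 140 and 144 CPM in controls 1 and 2, and Cd79a 1744 and 362. For erythroid genes the part lacking in control 2 was 0.01. These genes, in a list that shares no gene with the others, thus did not follow the difference between the controls. Erythroid or myeloid precursors, which divide and which the Ter119 and CD45 gate was meant to remove, may also contribute, since the erythroid median of -2.08 differs between the same groups. Fewer cycling dental cells in the knockout would give the same cell cycle median of -1.25, and these last 2 explanations cannot be told apart because blood genes and genotype change together.

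The second pattern is the higher level of dental mesenchyme genes. Fewer other cells in the knockout, with unaltered mesenchymal cells, would raise all mesenchymal genes alike. The collagen list had an upper quartile of -0.53, but 0.15 without control 2, and other cells also express collagens, so this stays open. A different mix of mesenchymal cells may be involved, with the periodontal ligament and tendon median at -1.90. Loss of Ptip within the same cells, or the Cre transgene itself, could also give the dental mesenchyme median of 0.67. These explanations cannot be told apart here, because bulk RNA does not separate the cells and each follows genotype.

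The third pattern is technical and may bear on which genes these counts can measure. Of 77 ribosomal protein genes, 2 had under 5 CPM, Rpl24 (0.93) and Rps10 (2.32), whereas the median was 88.9. They have 5 and 3 near-identical copies, against a median of 5, and Rpl26, also with 5, had 86.3 CPM. Gapdh, with 78, had 50.0 to 53.9 CPM. If shared reads were lost, CPM should have been lower for genes with more copies. Spearman's rho across genes was -0.10 (permutation p = 0.373, adjusted p = 0.431). If an aligner that does not split reads met short exons, CPM should have grown with the longest exon, and rho was 0.091 (permutation p = 0.431, adjusted p = 0.431). The number of copies thus does not set the 2 genes apart. Neither relation was found, but the intervals reach -0.32 and 0.31, and how closely each copy matches was not tested, so both explanations stay open, and no biological explanation was tested. A related gap is in the mitochondrial genes, where mt-Co2 had 0.84 to 1.59 CPM and mt-Cytb 1674 to 3696.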
